A study of Homo sapiens with 6 samples.

How the data were processed

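RNA from 6 cultures of khES3 or khES3-derived cells was labelled with biotin and hybridised to Affymetrix 3' expression arrays, 1 array per group, per the labels' protocols. The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set, per the submitters' processing notes, which name MAS5 without a version; detection calls, software version and further filters are not given in the sources used here. MAS5 summarises each probe set on its own array. In the deposited intensities each of the 6 columns had a 2% trimmed mean of about 500.1, so the arrays had been brought to 1 target before deposit. No value was missing, and no column of per-sample values was left unused.

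Each array was multiplied by 1 factor that makes the 2% trimmed means equal, which moved no value by more than 0.00105%. A floor of 80.3 signal units, the mean over arrays of the array medians, was applied, and log2 was taken. A gene counted as measured in a comparison if at least 1 of its 2 arrays was at or above the floor; with 1 array below it the difference is a bound, written "at least". Folds are ratios of these floored signals, and a gene was called 2-fold apart at an absolute log2 difference of 1 or more. With 1 array per group no p-value, standard error or replicate spread exists.

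Of the 54675 probe sets, 41097 have 1 gene symbol in the platform annotation used here, 1801 have several and 11777 are not listed with a gene. Gene identifiers of 41043 probe sets matched the reference gene table, and no symbol needed updating. Each of 19775 genes was represented by its single-gene probe set with the highest mean log2 level over the 6 arrays, and 10523 genes had more than 1. Other probe sets of a named gene are cited only where they were at or above the floor on both arrays, and not for every such gene. POU5F1 has no value under these rules and was not analysed here.

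Before the data were examined, 23 gene lists, the comparisons, 8 alternative settings and the rule for named genes were fixed; 1 of the lists is not reported here. The rule names genes of the pluripotency, endoderm, methionine and amino acid response programmes (NANOG, SOX2, CDKN1A, MAT2A, MAT2B, AHCY, ASNS, DDIT3, TRIB3, ATF4, SOX17, FOXA2, CXCR4 and GATA6). It adds up to 2 members at each end of each list that was apart from matched genes or had at least 2 members 2-fold apart. It also adds the 6 genes highest and the 6 lowest outside the lists, above the floor on both arrays with all their other probe sets in the same direction. For the deprivation comparisons those differences also had to exceed every difference among the 3 arrays with methionine. LOC and open reading frame names were skipped, and the text gives part of the genes that the rule names.

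A list's median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Outside the central 95% of these it was called apart from matched genes, as a description of these arrays. Correlations between differences were computed across genes, and overlaps were set beside the number that independent lists would share. None of the pairs of main comparisons shared an array.

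These alternative settings were the values as deposited, quantile normalization, differences centred on their median, floors of 40.1 and 161, a pseudocount in place of the floor, the median over a gene's probe sets, and the mean of the 3 arrays with methionine as control. A further alternative, a 2-fold difference against each of these 3 arrays, was added after the data were seen, as were 5 further gene lists used in the closing section (germline, imprinted, YAP and TGF-beta targets, metallothionein and ZNF genes).

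The calculation was tested on simulated arrays of 19775 genes for the 24 h deprivation comparison. Their spread at each level was taken from the difference between the 24 h complete and 0 h arrays. The shifted genes were drawn only from those over 4 times the floor, so recovery of dimmer genes was not examined. Of genes shifted by 1.5 on the log2 scale 88% were called 2-fold higher. Of those shifted by -1.5, 94% were called 2-fold lower, and of genes shifted by 2.5 or -2.5 100% were called. Of unchanged measured genes 7.02% were called 2-fold apart, against 3.83% of genes between the real 24 h complete and 0 h arrays. The simulation thus gave more such genes than the pair it was modelled on, and 7.02% does not estimate the false calls in these data. Part of each count still reflects the spread between arrays. Of 200 random lists 4% were called apart. The simulated spread was independent between probe sets, so 4% is not the rate for lists of genes that vary together. In the real data, lists were also apart between arrays with methionine, as given below. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.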

Results

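Gene expression was measured on 6 arrays of khES3, an established human embryonic stem (ES) cell line. Undifferentiated cells were sampled at 0 h, and after 5 h or 24 h in complete medium or in medium without methionine, the amino acid from which cells make S-adenosylmethionine, the donor for methylation reactions. The array labelled endoderm came from khES3 cells differentiated with activin A for 5 days. Each of the 6 groups had 1 array, so no difference below has a replicate check and no significance test between groups was run. The number of arrays limits the precision of every value. Between 46.3% and 52.7% of the 54675 probe sets were at or above a floor of 80.3 signal units, and 12142 to 13362 genes were at or above it on an array. The 3 arrays of undifferentiated cells with methionine gave the size of difference seen without deprivation. Among genes with a mean level over 16 times the floor, the 95th percentile of the absolute log2 difference between them was 0.63 for 5 h against 0 h, 0.57 for 24 h against 0 h and 0.64 for 24 h against 5 h. For genes at 1 to 4 times the floor these percentiles were 1.16, 1.08 and 1.24.

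After 5 h without methionine, genes of the amino acid response, which the transcription factor ATF4 controls, were higher than in complete medium. CHAC1, which degrades glutathione, was 6.74-fold higher (signal 2294 against 340.5), the cystine transporter SLC7A11 was 5.97-fold higher, the pseudokinase TRIB3 5.53-fold and asparagine synthetase, ASNS, 3.24-fold (5013 against 1549). DDIT3 was 2.53-fold higher and ATF4 itself 1.55-fold. EGR1, an immediate early transcription factor, was 13.0-fold higher (5766 against 442.2), and CDKN1A, an inhibitor of cyclin-dependent kinases, 3.13-fold. Compared with the 0 h array, CDKN1A on the 5 h deprived array was higher by 0.97 on the log2 scale, under 2-fold. PRDM14, a regulator of pluripotency, was 2.57-fold lower (4968 against 12746), while NANOG (log2 difference -0.31) and SOX2 (-0.08) were less than 2-fold apart. The 28S rRNA 5' control probe set read 30181 on the 5 h deprived array and 13298 on the 5 h complete array, and this stands beside each gene group of the comparison. In all, 712 genes were at least 2-fold higher and 338 at least 2-fold lower among 13919 measured genes, 7.54% against 3.83% to 6.45% between pairs of arrays with methionine.

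The amino acid response list had the highest median of the 23 lists at 5 h. Its 34 measured members had a median log2 difference of 1.13, 19 were at least 2-fold higher, none was 2-fold lower, and all 34 were above 0. That median lay at the 100th percentile of 10000 random lists matched on expression, a description of these arrays only. Members nearest to 0 were CTH (0.16, but -0.09 by its other probe set) and SLC7A3 (0.20). The aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a median of 0.25 over 17 genes, with CARS1 2.25-fold and SARS1 1.84-fold higher and RARS1 1.70-fold lower. Serine and folate one-carbon genes had a median of 0.29 over 13 genes, and SHMT2, the mitochondrial serine hydroxymethyltransferase, was 2.49-fold higher with both of its other probe sets in the same direction. With a floor of 40.1, this median was 0.15, inside the matched range.

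Immediate early and MAPK feedback genes had a median of 0.73 at 5 h, with 8 of 19 at least 2-fold higher. Besides EGR1, whose other probe set gave 3.56, IER3 was 4.59-fold higher, and SPRY2 (-0.26) and DUSP6 (-0.18) were lowest. Nodal and activin targets had a median of 0.37 over 7 genes, led by NODAL at 0.83, but GDF3 was 3.37-fold lower. That list was inside the matched range with a floor of 40.1 or 161 and with the median over probe sets.

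Cell cycle, pluripotency and cholesterol synthesis genes were lower than matched genes at 5 h. The control array itself differed from 0 h for some of these lists. On the 5 h complete array the G1/S list was at 0.23 against 0 h, above the matched range. Pluripotency was at 0.21 (97.2nd percentile) and G2/M at 0.06, both inside it, and cholesterol synthesis was at -0.28, below it. The G1/S and DNA replication list had a median of -0.40 over 19 genes with none 2-fold apart, and RRM2, a subunit of ribonucleotide reductase, was at -0.86. For the G2/M and mitosis list the median was -0.32 over 21 genes. HMMR was 2.21-fold lower and CDK1 was at -0.95. MKI67 was 3.75-fold higher by the probe set that represents it, but at -0.29 by the median over its probe sets. The pluripotency list had a median of -0.31, with 20 of 21 genes less than 2-fold apart; PHC1 was at -0.82 and LIN28B at 0.03. Cholesterol synthesis had a median of -0.39 over 13 genes, with HMGCS1, the cytosolic HMG-CoA synthase, 2.72-fold lower and IDI1 at -0.95.

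The methionine cycle and polyamine list stayed inside the matched range at 5 h (median -0.09, 28.5th percentile), with none of 23 genes 2-fold apart. MAT2A, the enzyme that makes S-adenosylmethionine in most cells, was 1.62-fold higher (33559 against 20688), but its other probe set gave -0.31. MAT2A was also 2.61-fold higher in complete medium at 5 h than at 0 h, and against the mean of the 3 arrays with methionine its 5 h log2 difference was 1.60. MAT2B (-0.54) and AHCY (-0.34) were less than 2-fold apart. Outside the lists, the genes highest at 5 h were GADD45B (9.42-fold, with both of its other probe sets higher), NHLH2 (9.31-fold), H2AC6 (8.72-fold), CSRNP1 (8.34-fold), ZNF750 (8.25-fold) and CCN2 (6.17-fold). H2AC6 belongs to the histone H2A family, whose members share sequence, so its value is uncertain. The genes lowest outside the lists were CA5BP1 (6.04-fold), SLC5A3 (5.86-fold), FANCL (5.63-fold), ZNF33B (5.53-fold), HSD17B1 (5.23-fold) and DECR2 (5.12-fold). CA5BP1 is a pseudogene copy, and its value is uncertain for the same reason.

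**Figure D1:**
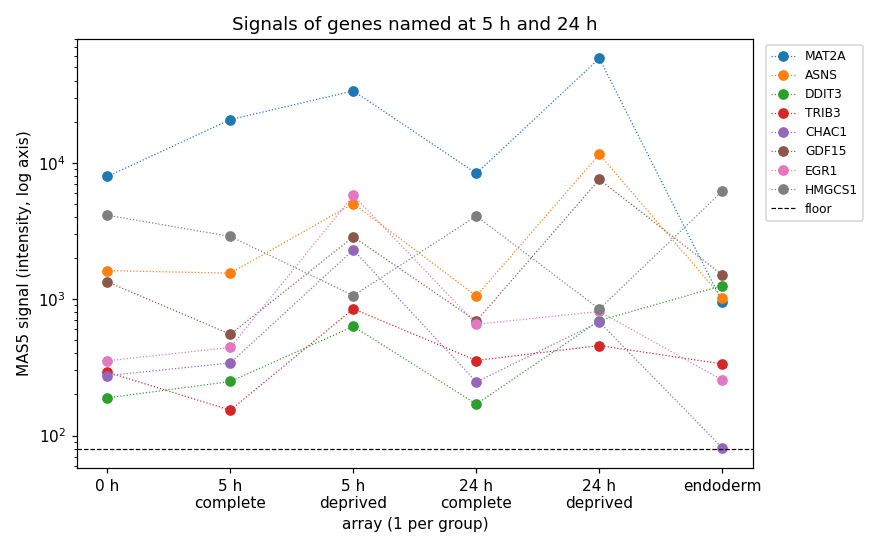
Each point is the MAS5 signal (log axis) of 1 gene on 1 array, dotted lines join a gene's values by eye only, and the dashed line is the floor of 80.3; levels are to be compared within a gene. ASNS was at 5013 and 11509 on the 5 h and 24 h deprived arrays and at 1549 and 1053 on the matching complete-medium arrays.

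After 24 h without methionine, MAT2A was 6.97-fold higher than in complete medium (58117 against 8337), with 2.39 on the log2 scale by its other probe set. ASNS was 10.9-fold higher (11509 against 1053), as was GDF15, a secreted stress-response cytokine (7531 against 691), and DDIT3 was 4.09-fold higher. TRIB3 (0.37) and CDKN1A (0.16), both over 3-fold higher at 5 h, were less than 2-fold apart at 24 h. DNMT3B, a de novo DNA methyltransferase abundant in ES cells, was 2.22-fold lower (31462 against 69815; log2 difference -0.96 after quantile normalization), and SOX2 was at -0.92 while NANOG was at -0.20. HMGCS1 was 4.80-fold lower, although its other probe set gave 0.37 and the median over both gave -0.95.

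The number of genes at least 2-fold apart at 24 h was 2344 of 14321 measured genes, or 16.4%, with 837 higher and 1507 lower. Over genes at or above the floor on both arrays the median log2 difference was -0.15, a shift to set beside each 24 h difference; percentiles among matched lists are not affected by it. Once differences were centred on that median, 1146 genes were higher and 1059 lower, a share of lower genes of 48.0% against 64.3% without centring. On the 24 h deprived array the actin 3'/5' signal ratio was 7.59, that of GAPDH was 1.51, and the 28S rRNA 5' control probe set read 43005. On the 24 h complete array they were 25.5, 2.68 and 13817, and these RNA controls stand beside every gene group of this comparison.

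The amino acid response list had a median of 0.72 at 24 h, at the 100th percentile of matched lists, with 13 of 33 genes at least 2-fold higher and none 2-fold lower. VLDLR (-0.75) and ADM2 (at or below -0.28, a bound) were lowest. The aminoacyl-tRNA synthetases had a median of 0.43 over 17 genes, with AARS1 2.62-fold and SARS1 2.03-fold higher but VARS1 2.26-fold lower. Immediate early and MAPK feedback genes had a median of 0.49, with 5 of 19 at least 2-fold higher; IER3 was 5.43-fold higher and SPRY4 was at -0.86.

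Cholesterol synthesis was the only list of the 23 below matched genes at 24 h, with a median of -1.12 over 13 genes and 7 at least 2-fold lower. DHCR7, which makes the last step to cholesterol, was 3.51-fold lower with its other probe set at -0.58. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, went the other way at 3.29-fold higher, with both of its other probe sets higher. The pluripotency list had a median of -0.43 at the 4.49th percentile, inside the matched range, and 5 of 21 genes were at least 2-fold lower; against the mean of the 3 arrays with methionine it was at the 1.14th percentile. UTF1 was 3.66-fold lower, whereas ZFP42 (0.99) and USP44 (0.61) were highest. In the methionine cycle and polyamine list (median -0.20), 2 genes were 2-fold higher and 4 were 2-fold lower. SAT1, which acetylates polyamines, was 2.78-fold higher with MAT2A, and CBS, which starts the route from homocysteine to cysteine, was 3.69-fold lower although only 1 of its other 2 probe sets was lower.

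Single members of other lists were far apart at 24 h although their lists were inside the matched range. APOA2, an apolipoprotein, was 16.4-fold higher (2584 against 157.9) with its other probe set at 3.16, and TF, of the same list, was 2.05-fold lower. TWIST1, a mesenchymal transcription factor, was at least 18.6-fold higher and ACTA2, also of the fibroblast list, 2.15-fold lower. SUV39H1, a histone H3 lysine 9 methyltransferase, was at least 5.55-fold lower. The hypoxia and glycolysis list held ADM (4.43-fold higher) and NDRG1 (3.58-fold higher) beside PFKFB4 (5.54-fold lower) and BNIP3 (2405 against 9609, with -1.06 by its other probe set). Compared with the 0 h array, ADM on the 24 h deprived array was higher by only 0.58 on the log2 scale. HERPUD1, of the unfolded protein response, was 2.83-fold higher. HMMR was 3.98-fold and TPX2 2.49-fold lower in the G2/M list, and CCNE2 (522 against a signal under the floor) was higher in the G1/S list. The definitive endoderm list had a median of 0.01: CXCR4 was 2.43-fold higher, EOMES was 2.51-fold lower, SOX17 was at 0.07 and GATA6 at -0.25. The log2 difference of CXCR4, 1.28, was smaller than its spread of 1.69 among the 3 arrays with methionine.

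Outside the lists, VCX2 was 21.6-fold higher, CCN2 20.9-fold, the protocadherin PCDH8 17.2-fold, thrombospondin 1 (THBS1) 16.0-fold, the homeobox gene RHOXF1 14.5-fold and RASD1 14.4-fold. VCX2 belongs to a family of near-identical copies and its value is uncertain. The genes lowest outside the lists were TMEM158 (7.67-fold), CCM2L (100.8 against 706.3), the mitochondrial isocitrate dehydrogenase IDH2 (5.63-fold), LINC00458 (5.59-fold), COL13A1 (5.22-fold) and CLC (5.06-fold). The median over probe sets put CCM2L at -1.57 and COL13A1 at -0.65.

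Across the 10907 genes at or above the floor on all 4 arrays, the 5 h and 24 h differences correlated with a Pearson r of 0.23 and a Spearman rho of 0.21; genes are not independent replicates. Of 12881 genes measured in both, 130 were at least 2-fold higher at both times, where independent lists of these sizes would share 41.8, and 68 were 2-fold lower at both, against 37.8. GADD45B, CCN2, GDF15 and ASNS were among those higher at both times. Another 57 genes were higher at 5 h and lower at 24 h, against 77.9 for independent lists, and 19 the reverse, against 20.3. The 2 differences used different arrays.

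**Figure D2:**
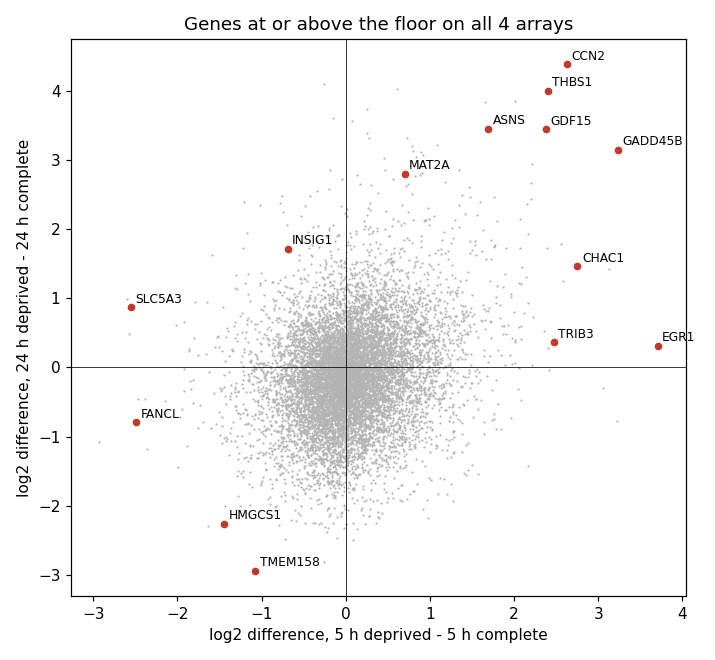
Each grey point is a gene at or above the floor on all 4 arrays, with its log2 difference between deprived and complete medium at 5 h (x axis) and at 24 h (y axis), 1 array per group; red points are named genes. CCN2, GADD45B and ASNS lie in the upper right, EGR1 (3.70 and 0.31) lies near 0 on the y axis, and HMGCS1 lies in the lower left.

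In endoderm, several markers of the definitive endoderm were among the genes farthest above the 0 h cells. CER1, a secreted Nodal inhibitor, was 284-fold higher (53047 against 186.8), GATA6 117-fold, the chemokine receptor CXCR4 80.9-fold with both of its other probe sets higher, FOXA2 at least 144-fold and SOX17 at least 80.1-fold. All 17 measured genes of the definitive endoderm list were at least 2-fold higher, with a median log2 difference of 5.52, and FOXA3 (1827 against 912.3) and GATA4 (at least 3.25-fold) were lowest among them. FOXA3 was at 0.94 with a pseudocount in place of the floor and GATA4 at 0.70 with a floor of 161, both under 2-fold. PRDM14 was 127-fold lower, SOX2 43.1-fold lower and NANOG 2.37-fold lower (10811 against 25669). In the pluripotency list 17 of 21 genes were at least 2-fold lower, with a median of -2.33; PODXL (0.50) and SALL4 (-0.29) were highest. In all, 2129 genes were at least 2-fold higher and 2605 at least 2-fold lower of 13852 measured. The endoderm array also stood apart in its RNA controls, with an actin 3'/5' ratio of 9.85 against 22.5 at 0 h and a 28S rRNA 5' signal of 31855 against 14080.

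Nodal and activin targets had a median of 1.81 over 8 genes, led by LEFTY1 (31.5-fold higher) and FGF17 (at least 16.3-fold), with GDF3 at -0.84. With a floor of 40.1 this median was 0.35, inside the matched range. Hypoxia and glycolysis genes had a median of 0.81 over 15 genes: P4HA1 was 6.34-fold and BNIP3 4.25-fold higher, and EGLN3 was 6.81-fold lower. The later endoderm and liver list had a median of 1.86 over only 6 measured genes, with APOA2 88.2-fold and APOA1 at least 72.4-fold higher but AFP at least 2.33-fold lower (-0.22 with a floor of 161). The list median was 0.035 with quantile normalization and -0.087 with a floor of 40.1.

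Replication and folate lists and, with the processing used above, the trophoblast list were below matched genes in endoderm. The G1/S and DNA replication list had a median of -1.45, with 15 of 19 genes at least 2-fold lower; CCND1 was 8.39-fold and MCM2 6.05-fold lower. The G2/M and mitosis median was -0.77, with TOP2A 4.64-fold lower, and against the mean of the 3 arrays with methionine this list was at the 2.56th percentile, inside the matched range. Serine and folate one-carbon genes had a median of -1.29, with 9 of 13 at least 2-fold lower; PSPH, the last enzyme of serine synthesis, was 16.3-fold and MTHFD1 7.66-fold lower. The trophoblast list had a median of -1.14 over 7 genes, with TFAP2C 8.92-fold lower but GATA3 at least 24.3-fold higher. It was inside the matched range under 6 of the 8 alternatives. The other 2, the values as deposited and centred differences, changed no list's call, so they do not support this one. MAT2A was 8.31-fold lower in endoderm and SRM, spermidine synthase, 4.61-fold lower, while the methionine cycle and polyamine list as a whole (median -0.54) was inside the matched range.

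Other genes of lists inside the matched range were far apart in endoderm. DNMT3L was 65.0-fold and DNMT3B 14.2-fold lower, and TET2 at least 7.64-fold higher. OTX2 was 47.4-fold higher and MYC 37.6-fold lower. In the amino acid response list, VEGFA was 8.93-fold and DDIT3 6.65-fold higher beside SLC7A1, 10.8-fold lower. THY1 was 27.0-fold lower and COL5A2 29.9-fold higher in the fibroblast list. Outside the lists RHOBTB3 (374-fold, with its other 3 probe sets higher), CST1 (310.5-fold), FOXQ1 (224-fold), PIK3R5 (174-fold), CST4 (139-fold) and EPSTI1 (95.7-fold) were highest. The lowest were MT1X (119-fold), APELA (90.9-fold), MT2A (90.5-fold), GAP43 (79.6-fold), MT1HL1 (73.5-fold) and MT1G (67.9-fold). The cystatins CST1 and CST4, and the metallothioneins MT1X, MT2A, MT1HL1 and MT1G, share sequence within their families, so single members are uncertain.

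**Figure D3:**
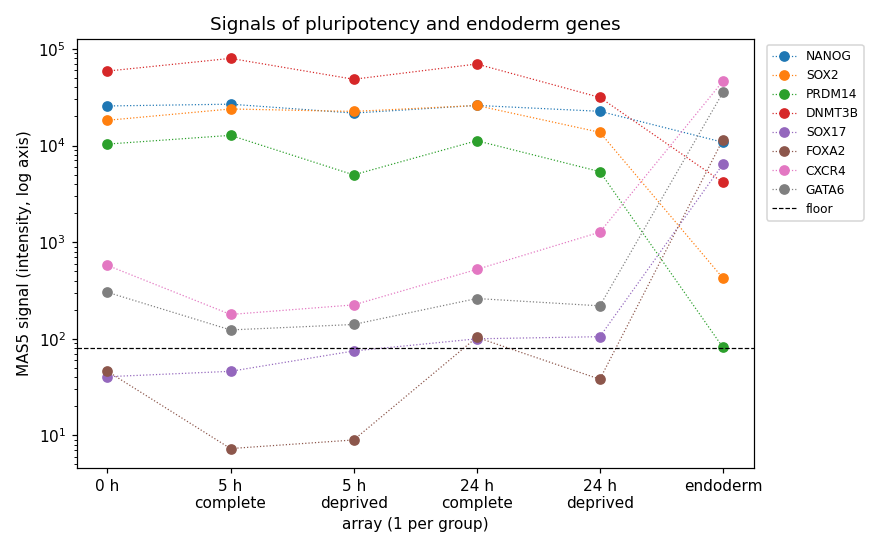
Each point is the MAS5 signal (log axis) of 1 gene on 1 array, dotted lines join a gene's values by eye only, and the dashed line is the floor of 80.3. GATA6 read between 123.4 and 302.8 on the 5 arrays of undifferentiated cells and 35471 in endoderm, and SOX2 read 13707 or more on those 5 arrays and 423.5 in endoderm.

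The deprivation differences correlated little with the endoderm difference across genes. Pearson r was 0.08 for 5 h over 10335 genes and -0.03 for 24 h over 10338 genes. At 5 h, 109 genes were 2-fold lower both without methionine and in endoderm, against 67.6 for independent lists. Another 124 were higher in both, against 100. In opposite directions, 135 were higher without methionine and lower in endoderm, against 137, and 54 the reverse, against 49.7. At 24 h, 123 genes were at least 2-fold higher both without methionine and in endoderm, against 116 for independent lists, and 351 were 2-fold lower in both, against 297. Another 241 were higher without methionine and lower in endoderm, against 153, and 249 the reverse, against 224. MAT2A and MYC were among the 241, and APOA2 and IER3 were higher in both. The 24 h deprived and endoderm arrays were also alike in their RNA controls, with actin 3'/5' ratios of 7.59 and 9.85. This stands beside these overlaps.

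In complete medium, 678 genes were at least 2-fold apart between 5 h and 0 h, 541 between 24 h and 0 h, and 919 between 24 h and 5 h. The share of these that was lower was 72.4%, 38.6% and 19.8%, and 62.0%, 48.8% and 35.1% after quantile normalization. The amino acid response list was lower at 5 h (median -0.21) and 24 h (-0.34) than at 0 h. Hypoxia and glycolysis genes had a median of -0.53 at 5 h and 0.04 at 24 h against 0 h, with none of 15 above 0 at 5 h. The fibroblast list was at -0.40 and -0.74, cholesterol synthesis at -0.28 and -0.10, and ribosomal proteins at 0.14 and 0.29. Lists thus left the matched range without deprivation too. At 5 h against 0 h, the amino acid response, hypoxia and glycolysis, fibroblast and cholesterol synthesis lists were among those below it. At 24 h against 0 h, the amino acid response and fibroblast lists were among those below it, and ribosomal proteins were above it.

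**Figure D4:**
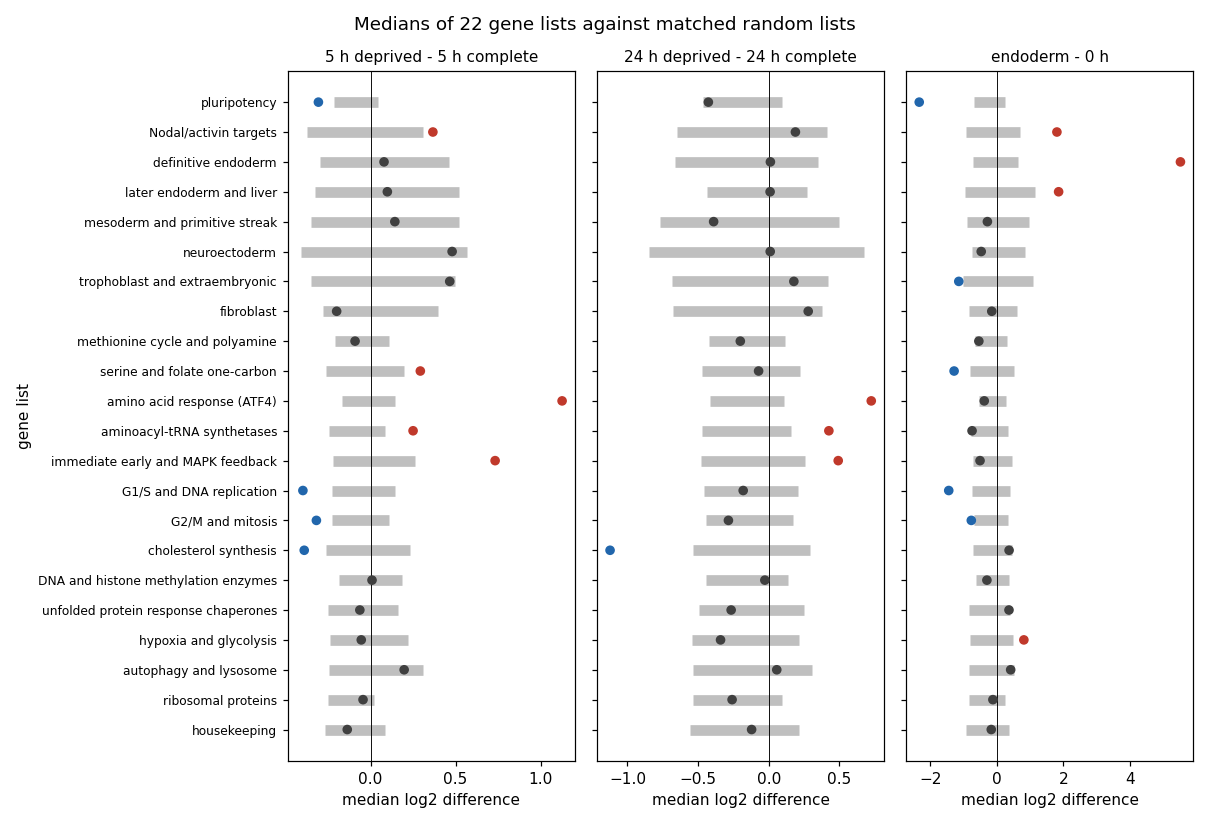
Points are the median log2 difference of 22 gene lists in the 3 main comparisons, red above and blue below the central 95% of 10000 matched random lists (grey bars), and dark grey inside it; x axes differ between panels. The amino acid response list lies at 1.13 and 0.72 without methionine, cholesterol synthesis at -1.12 at 24 h, and the definitive endoderm list at 5.52 in endoderm.

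A further 8 lists were inside the matched range in all 3 main comparisons with the processing used above. Their medians at 5 h, 24 h and in endoderm were 0.14, -0.39 and -0.28 for mesoderm and primitive streak, 0.48, 0.01 and -0.47 for neuroectoderm, -0.20, 0.28 and -0.15 for fibroblast, and 0.01, -0.03 and -0.30 for DNA and histone methylation enzymes. For unfolded protein response chaperones they were -0.06, -0.27 and 0.37, for autophagy and lysosome 0.20, 0.06 and 0.42, for ribosomal proteins -0.04, -0.26 and -0.12, and for housekeeping genes -0.14, -0.12 and -0.17.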

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

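The tests of scaling at 24 h, given here, were chosen after the result was seen; the test of probe position was written before it.

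FLRT3, of the definitive endoderm list, had a log2 difference of -1.02 at 5 h (a bound, as the deprived array was under the floor) and 1.04 at 24 h. Its other probe set was at 0.23 at 5 h and 0.56 at 24 h, so the lower value at 5 h rests on 1 probe set, and the difference between the times was not tested. The 28S rRNA 5' control probe set, which no comparison uses, read 2.27 times higher on the deprived than on the complete array at 5 h and 3.11 times higher at 24 h. The actin 3'/5' ratio was 3.36 times higher on the 24 h complete array than on the 24 h deprived array.

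More genes were 2-fold lower (1507) than higher (837) at 24 h without methionine. Against the mean of the 3 arrays with methionine, 991 were lower and 762 higher, a share of lower genes of 56.5%. When 2-fold was asked against each of those 3 arrays, 531 were lower and 450 higher. The size of the excess thus varied with the control. A candidate explanation is the scaling between arrays. Quantile normalization, which makes the arrays' signal distributions equal, left the share of lower genes at 64.1% (exact 95% interval 62.1% to 66.0%, taking genes as independent), while it moved that between the 24 h and 5 h complete arrays from 19.8% to 35.1%. That argues against scaling as the whole cause as far as equal distributions can be assumed. Centring gave 48.0%, under the 55% set for scaling as the cause, so that prediction was met. It does not even out every split: with centring the share was 35.4% at 5 h of deprivation and 30.3% between the 24 h and 5 h complete arrays. But it removes a shift of the median whatever its source, so it cannot tell scaling from lower levels of many transcripts. Quantile normalization and centring thus differed, and scaling stays open as an explanation. Another is the position of the probe sets in the transcript, since the actin ratio differed: the 779 other probe sets of the lower genes had a median centred difference of -0.45, between the bounds of -0.25 and -0.5 set before the test, and 74.3% of them were below 0. Scaling, probe position and an effect of deprivation on many transcripts cannot be told apart with 1 array per group.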

How the results depend on the processing

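The alternative that asks for 2-fold against each of the 3 arrays with methionine was chosen after the result was seen, the others before it.

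The values as deposited moved no call. The amino acid response median kept its direction and stayed above the matched range under all 8 settings fixed before the data were seen, at 1.10 to 1.34 at 5 h and 0.61 to 0.90 at 24 h. Centring leaves the percentiles of lists unchanged, so it and the values as deposited do not test this call. Counts moved with the floor, since a lower floor admits dimmer probe sets and a higher one removes them. With a floor of 40.1, 1456 genes were higher and 909 lower at 5 h, 1377 and 2411 at 24 h, and 1852, 1865 and 2427 were apart in complete medium (5 h against 0 h, 24 h against 0 h, 24 h against 5 h). With a floor of 161, the 5 h counts were 438 and 201, and those in complete medium 302, 181 and 404. Against the mean of the 3 arrays, 762 genes were higher and 991 lower at 24 h. With that control the correlation of the 5 h and 24 h differences was 0.33 (the control arrays are then shared). The pluripotency median at 24 h was then -0.47, below the matched range. Against each of the 3 arrays, 263 genes were higher and 169 lower at 5 h, and 450 and 531 at 24 h. The later endoderm and liver median in endoderm turned from 1.86 to 0.035 with quantile normalization and -0.087 with a floor of 40.1. With the median over probe sets, GATA2 at 24 h was -0.83 and MKI67 at 5 h -0.29, because other probe sets of these genes went the other way. Unless a reason is given, the cause was not tested. No paired analysis was possible within a comparison because each group has 1 array. Dim genes limit what these arrays show: at 1 to 4 times the floor, 11.9% of genes were 2-fold apart between the 24 h and 5 h complete arrays, against 1.00% over 16 times the floor.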

Other observations

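The tests of paralogs, of a rise of all dim genes and of RNA coverage were chosen after the result was seen; the class tests of germline and ZNF genes, and the floor and scaling tests of ZNF genes, were written before it. All 5 lists were made after the data were seen, and the germline list leaves out DAZL, VCX2 and RHOXF1, which had been seen first, and the YAP and TGF-beta list leaves out CCN2 and THBS1, named above; the metallothionein list holds genes whose values had been seen, such as MT2A.

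Metallothioneins, small metal-binding proteins, had a median log2 difference from 0 h of 0.84 at 5 h and 0.97 at 24 h in complete medium, above the matched range. Between deprived and complete medium the median was 0.88 at 5 h, with 8 of 8 members above 0 (MT1M 2.42-fold and MT2A 1.98-fold higher), and -0.16 at 24 h, inside the matched range with 1 of 9 members above 0, and in endoderm the median was -6.50. Against the mean of the 3 arrays with methionine, 7 of 8 were at least 2-fold higher at 5 h (median 1.13), and the 24 h median was 0.17, still inside the range but with 9 of 9 above 0. Sequence shared within the family means that these are not independent values. Targets of YAP and TGF-beta signalling had medians of 0.52 at 5 h and 0.41 at 24 h of deprivation, both above the matched range, and -0.29 in endoderm; against the mean of the 3 arrays with methionine the medians at 24 h (0.14) and in endoderm (0.28) were inside it. CCN1 was 2.55-fold and 5.08-fold, AJUBA 4.23-fold and 1.33-fold, and ID2 1.48-fold and 6.60-fold higher at 5 h and 24 h, whereas FJX1 was at -1.10 at 5 h and SMAD6 at or below -1.66 (a bound) at 24 h, when 12 of 19 members were above 0. Imprinted genes had a median of 0.36 at 24 h (99.1st percentile), with MEG3 5.52-fold, NNAT 3.28-fold and PEG3 2.87-fold higher but KCNQ1 at least 2.81-fold lower. They were inside the matched range at 5 h (-0.05) and, with the median over probe sets, at 24 h (0.11). In endoderm the median was 0.14, inside it, but 0.99 with the floor doubled and 0.74 against the mean of the 3 arrays, both above it. The imprinted list does not hold CDKN1C, which was 13.3-fold higher at 24 h without methionine (15125 against 1136). All 3 of its other measured probe sets were higher as well.

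Germline and cancer-testis genes, mostly silent outside germ cells, were higher at 24 h without methionine. Of 68 listed genes, 55 had a probe set and 41 were measured, while genes under the floor on both arrays have no value. Some, such as BRDT (176 against 69.3), were measured only through the deprived array. Of the 41, 18 were at least 2-fold higher and 3 were 2-fold lower. TDRD6 (2.37), TEX14 (2.24), TDRD1 (2.01) and MAEL (1.97) were on the high side, and DPPA5 (-1.61) and TEX19 (-1.51, a bound) on the low side. At 5 h none of 36 was 2-fold apart, and the median was 0.05. In the same 24 h comparison DNMT1 was at -1.13 and DNMT3B at -1.15, but DNMT3L at 0.75 and DNMT3A at 0.27 (1 of its other 2 probe sets was lower).

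The hypothesis that germline genes were higher as a class at 24 h was tested on a list without DAZL, VCX2 and RHOXF1, which had been seen first: the median was 0.80, above all 10000 matched lists. A rise of all dim genes is argued against, since 12 of 33 germline genes under 2 times the floor with methionine passed that level (36.4%, exact 95% interval 20.4% to 54.9%) and 305 of 8363 other such genes did (3.65%, 3.26% to 4.07%), a ratio of 9.97; the interval treats genes as independent. Probe sets shared between paralogs are argued against as the whole cause, because without the multi-copy families the median was 0.62. Unequal RNA coverage stays open: the endoderm array, with the nearest actin ratio, gave -0.68 (-1.39 with the floor doubled), but its cells differ in type. An effect of deprivation stays open too, untested.

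ZNF33B was among the lowest genes at 5 h, while ZNF750 was among the highest (8.25-fold). The ZNF list keeps both of these genes, named above. The hypothesis that ZNF genes were lower as a class was not borne out. The median of 420 ZNF genes was 0.25, above all 10000 matched lists, with 52 at least 2-fold higher and 5 lower. Leaving the range was not particular to deprivation: between arrays with methionine the list was at the 99.7th percentile at 5 h against 0 h, the 0.53rd at 24 h against 0 h and the 0.03rd at 24 h against 5 h. The explanations prepared for a lower class, dim probe sets and scaling, therefore had nothing to explain: the median was 0.28 with the floor doubled and 0.20 at the lower of quantile normalization and centring. At 24 h the ZNF median was 0.19, also above the matched range, and in endoderm it was -0.30, below it (-0.19 and inside it with the median over probe sets).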
